A study of Ovis aries with 16 samples.

How the data were processed

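Messenger RNA of the myocardium, the muscle of the heart wall, was sequenced in 16 adult female sheep, with 4 animals in each of 4 groups. Per the labels' protocols, poly-A RNA was purified from total RNA with oligo-dT beads and made into libraries with the TruSeq RNA kit. The deposited table held FPKM values computed by the authors, which are fragment counts divided by transcript length and by the number of fragments mapped in the library, with 1 column per animal. Per the submitters' processing notes, the tools were FastQC, TopHat2 2.0.9, Bowtie2 2.1.0, Cufflinks and Cuffdiff 2.1.1, and the genome build was Oar_v3.1. The notes as used here gave these names without their order or settings. Filters, and any further scaling between libraries, were not given in the sources used here. The column names matched the sample titles, and no column belonged to another sample.

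FPKM values are not read counts, so no count model was used. The table held 27054 features, of which 20926 were above 0 in at least 1 library. A feature entered the tests when its FPKM was at least 1 in at least 4 of the 16 libraries, which left 13251 features. The values as deposited were transformed to log2(FPKM + 1), and log2 differences are on that scale, which understates the change of features of low level. The group means of all 16 libraries were fitted together with limma 3.58.1 in R 4.3.3, with a trended prior variance. The fit had 12 residual degrees of freedom, and the prior added 2.36. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each contrast, with a false discovery rate of 0.05. The 8 contrasts were the 5 pairwise differences described below, the effect of prenatal BPA averaged over diets, the effect of overfeeding averaged over prenatal treatments, and the interaction. Figures and library summaries were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

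The features carried Ensembl sheep gene IDs, and the table did not pair them with gene names. The gene table at hand, of assembly ARS-UI_Ramb_v3.0, held no Ensembl IDs, and 0 of the 27054 IDs matched it. For this reason none of the 37 gene lists fixed before the data were examined was tested, nor were the cardiac and metabolic genes chosen then to be reported by symbol. The rule fixed at that time named the 10 called genes with the largest change in each direction, or the genes with the smallest p where few were called. With no names and no calls, it was reduced after the data were examined to the 2 features with the smallest p in each direction of each contrast, given by ID and as values that did not pass.

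The FPKM table gives no depth of the libraries. For features of low level, an FPKM value is a whole multiple of the value of 1 read, and the ratio of these steps between libraries gave a relative depth for the 12 libraries numbered 1 to 3. Steps were called equal within 0.01 on the log2 scale. The 4 libraries numbered 0 shared no common step with the others and could not be placed on that scale, and the absolute depth stayed unknown. A value of 0 in such a table can be a failed estimate as well as an absence of reads, so features are described as listed at 0, with each library's value.

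The procedure was tested on simulated data made from the means and residual spread of the 13251 features, with 50 features changed at each of 4 sizes of change. Features varied independently there, without the differences between libraries described below, so the real libraries may allow less. The features of all 4 sizes were changed together, and many true changes ease the Benjamini-Hochberg threshold. A 2-fold change in only a few features would thus be recovered less often than these shares. Of the features changed 2-fold, it recovered 88% for BPA against control, 86% for ObBPA against obese, 76% for obese against control, 78% for ObBPA against BPA and 80% for ObBPA against control. At 1.5-fold, the shares recovered were 46%, 40%, 34%, 44% and 36% in the same order. No pair of libraries held identical values, and their correlations on the log2 scale lay between 0.905 and 0.956. Alternatives fixed before the data were examined changed the pseudocount, the filter, the scaling between libraries, the variance model, the weights of the libraries, the set of libraries fitted and the blocking by replicate number, and left out each library in turn. Those chosen after seeing the data added a term for the libraries numbered 0, left these libraries out, combined that term with library weights or with leaving out control library 1, or filtered on the median FPKM.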

Results

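Myocardial transcriptomes were compared among 4 groups of female sheep that differed in prenatal exposure and postnatal diet. Pregnant ewes had received the plasticiser bisphenol A (BPA), a compound with oestrogenic activity, at 0.5 mg/kg per day by subcutaneous injection from day 30 to day 90 of gestation, or corn oil alone. From 14 weeks of age their daughters were kept on a control diet or overfed, and hearts were taken at 21 months. The groups were vehicle and control diet (control), prenatal BPA and control diet (BPA), vehicle and overfeeding (obese), and prenatal BPA and overfeeding (ObBPA), with n = 4 animals each. The libraries of each group were numbered 0 to 3.

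Similar numbers of features were measured in the 4 groups. An FPKM of at least 1 was reached by 12584 ± 241 features in control, 12644 ± 119 in BPA, 12643 ± 105 in obese and 12682 ± 128 in ObBPA hearts (mean ± SD, n = 4). The most abundant feature, ENSOARG00000000037, took between 20.0% of the summed FPKM in control library 0 and 48.5% in BPA library 2. The 10 most abundant features together took 58.7% to 72.9%. Among the 12 libraries numbered 1 to 3, the depth relative to control library 3 ranged from 0.539 in control library 1 to 1.75 in BPA library 3. Absolute depth is unknown. The table did not pair feature IDs with gene names, so features are given by ID.

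The libraries did not separate by treatment group on the first pair of principal components. Correlations of log2(FPKM + 1) between libraries had a median of 0.937 within groups and of 0.937 between groups. Control library 1 lay apart on the first component, which held 13.8% of the variance, with a loading of -0.88 against -0.13 to 0.27 in the other libraries. The 4 libraries numbered 0, 1 from each group, differed from the other 12 in 3150 of 13251 features by limma at a false discovery rate of 0.05. Of these, 345 were higher and 2805 lower in the libraries numbered 0, and the median log2 difference of all features was -0.15. After median-of-ratios scaling, 1601 features differed, 865 higher and 736 lower, with a median log2 difference of -0.014 over all features. Each group held 1 such library, so this difference was balanced over the treatments.

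**Figure D1:**
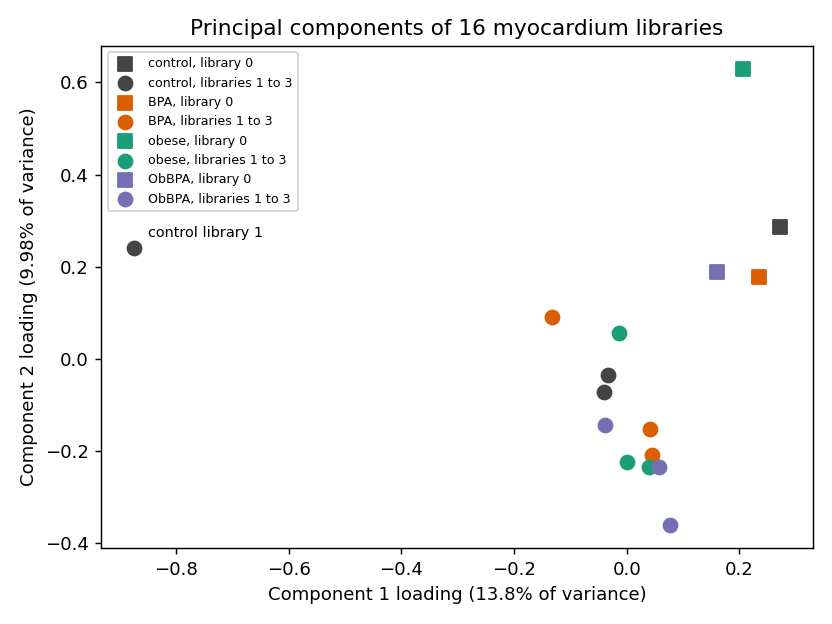
Loadings of the 16 myocardium libraries on the first (x axis, 13.8% of variance) and second (y axis, 9.98% of variance) principal component of log2(FPKM + 1), with a colour for each group and squares for the libraries numbered 0. Control library 1 lies at -0.88 on the first component, and the 4 squares lie at the upper right.

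The effect of prenatal BPA under the control diet was measured as BPA against control. The feature with the smallest p among those higher, ENSOARG00000004890, was listed at 0 in all 4 control libraries and had FPKM values of 1.69, 4.73, 2.91 and 1.08 in the BPA libraries. ENSOARG00000012812 had a mean FPKM of 7.53 ± 0.462 in control and 10.3 ± 0.810 in BPA hearts (SD, n = 4), a log2 difference of 0.40 ± 0.0889 (SE). ENSOARG00000014190 had 2.34 ± 0.444 in control and 0.852 ± 0.313 in BPA hearts (SD, n = 4), a log2 difference of -0.86 ± 0.169 (SE). ENSOARG00000012987 had 66.5 ± 8.11 and 44.1 ± 6.96 (SD, n = 4), a log2 difference of -0.59 ± 0.152 (SE). For each of these 4 features the libraries of the groups did not overlap, but the adjusted p was 0.999 by limma. Here and in the contrasts below, such a lack of overlap is likely for features picked by their small p. It is therefore no further evidence of a difference. No feature was called at a false discovery rate of 0.05 by limma. Evenly distributed p-values would put 663 of 13251 features under an unadjusted p of 0.05. By limma 324 features were under it, 186 higher and 138 lower. That count was 912 without control library 0 and 681 without control library 2. Without control library 0, the control group held no library numbered 0 while the other groups did. Every contrast that included control then also carried the difference of those libraries. Leaving out control library 2 or 3 gave control library 1 more weight in the control mean. The median SE of a log2 difference was 0.158. For 92.5% of features the 95% interval of the difference lay within a 2-fold change of FPKM + 1 in either direction. Here and in each contrast below, this bound is on FPKM + 1. It therefore does not bound the change in FPKM of features of low level. Among the 6092 features with a mean FPKM of at least 10, the share was 92.14%. With library weights estimated from the residuals 1 feature was called, ENSOARG00000003855. Control library 3 had a weight of 3.82 there, against 0.114 to 0.892 in the other control libraries. The FPKM values of this feature were 1.12, 0.346, 2.27 and 5.22 in control libraries 0 to 3 and 0.286 to 0.356 in the BPA libraries. Without ObBPA library 1, ENSOARG00000004890 was called.

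The same exposure was compared in overfed animals as ObBPA against obese. ENSOARG00000025092 was listed at 0 in all 4 obese libraries and had FPKM values of 10.1, 23.4, 18.2 and 23.5 in the ObBPA libraries. ENSOARG00000001688 had a mean FPKM of 24.8 ± 1.91 in obese and 52.8 ± 12.1 in ObBPA hearts (SD, n = 4), a log2 difference of 1.03 ± 0.201 (SE). ENSOARG00000021045 had 13.0 ± 2.20 in obese and 4.55 ± 3.21 in ObBPA hearts (SD, n = 4), a log2 difference of -1.48 ± 0.319 (SE). ENSOARG00000024106 had values of 17.7, 9.47, 3.35 and 4.86 in the obese libraries and was listed at 0 in all 4 ObBPA libraries. In the groups not compared its values were 5.45, 0, 0 and 4.19 (control) and 5.08, 0, 0 and 2.39 (BPA). The adjusted p by limma was 0.86 for the first pair and 1 for the second. No feature was called by limma, and 260 had an unadjusted p under 0.05, 148 higher and 112 lower, or 424 without control library 1. For 92.53% of features the 95% interval lay within a 2-fold change. ENSOARG00000025092 was called when only these groups were fitted and when BPA library 1 was left out, in the latter with an adjusted p of 0.000946 by limma, against a range of 0.000946 to 1 over its alternatives.

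**Figure D2:**
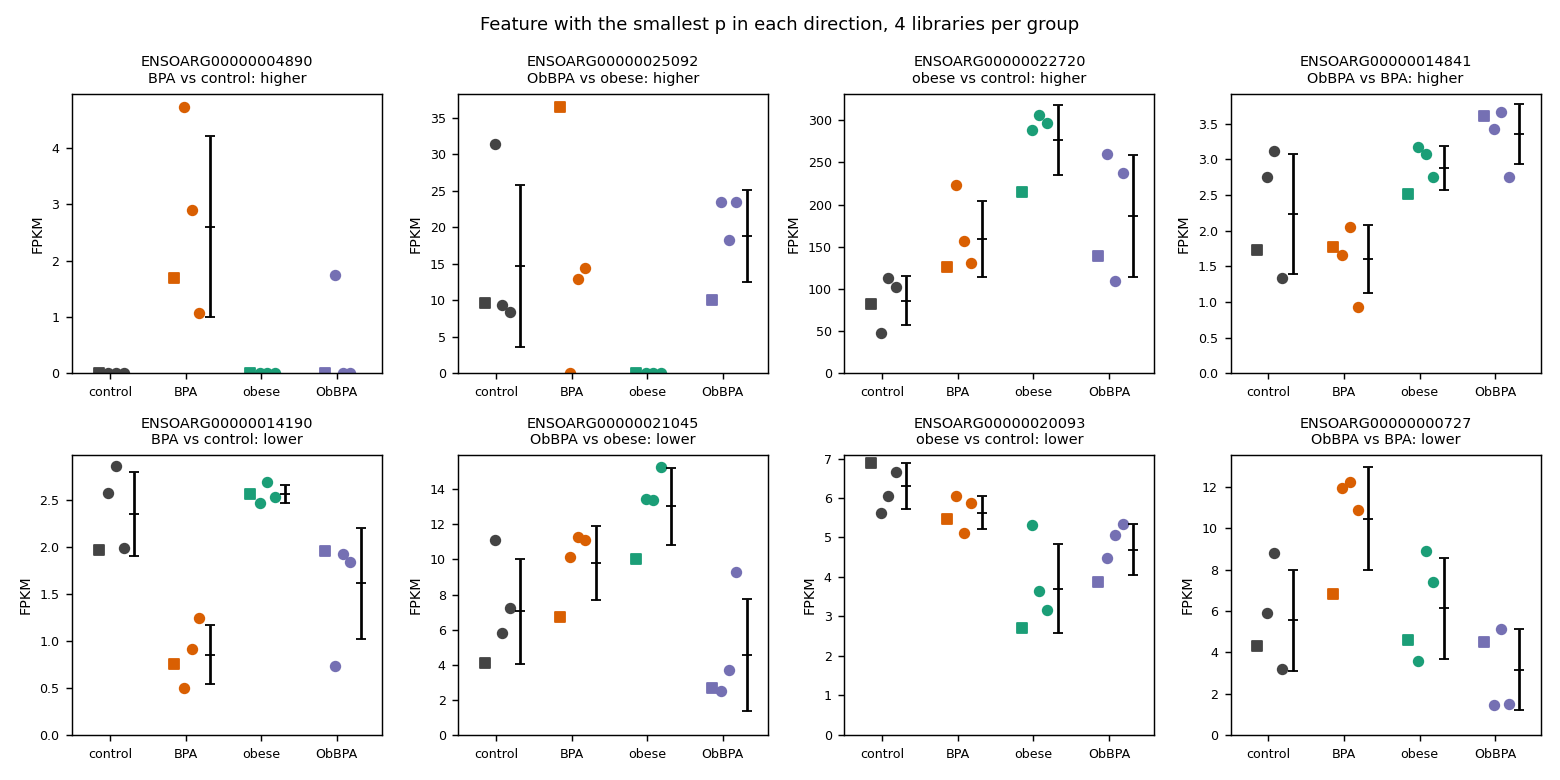
FPKM (y axis) of the feature with the smallest p in each direction for 4 pairwise contrasts, in the 4 libraries of each group (x axis). Points are libraries, with squares for those numbered 0, and bars show the mean ± SD; ENSOARG00000022720 had means of 86.1 in control and 276 in obese hearts, and none of the features passed the false discovery rate.

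Overfeeding without prenatal BPA was measured as obese against control. The feature with the smallest p in this contrast, ENSOARG00000022720, had a mean FPKM of 86.1 ± 28.9 in control and 276 ± 41.5 in obese hearts (SD, n = 4), with 159 ± 44.8 in BPA and 186 ± 72.8 in ObBPA hearts. Its log2 difference between obese and control was 1.73 ± 0.305 (SE), with an adjusted p of 0.685 by limma, and all 4 obese libraries lay above all 4 control libraries. ENSOARG00000001110 had 1.96 ± 0.479 in control and 3.67 ± 0.888 in obese hearts (SD, n = 4), a log2 difference of 0.65 ± 0.132 (SE). ENSOARG00000020093 had 6.30 ± 0.573 in control and 3.70 ± 1.13 in obese hearts (SD, n = 4), a log2 difference of -0.66 ± 0.139 (SE). ENSOARG00000025092, listed at 0 in the obese libraries, had values of 9.66, 31.4, 9.38 and 8.46 in the control libraries. The adjusted p of these 3 features was 0.834 by limma. No feature was called by limma, and 590 had an unadjusted p under 0.05, 336 higher and 254 lower. That count was 1535 without control library 0 and 1155 without control library 2, and it was 396 without control library 1. For 91.86% of features the 95% interval lay within a 2-fold change. With library weights 6 features were called, with only these groups fitted 4 were, and without control library 3 or without BPA library 1 there was 1.

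Overfeeding after prenatal BPA was measured as ObBPA against BPA. ENSOARG00000014841 had a mean FPKM of 1.60 ± 0.477 in BPA and 3.36 ± 0.421 in ObBPA hearts (SD, n = 4), a log2 difference of 0.76 ± 0.176 (SE). ENSOARG00000021237 was listed at 0 in all 4 BPA libraries and had values of 36.3, 22.5, 26.2 and 67.8 in the ObBPA libraries. In the groups not compared its values were 71.0, 0, 0 and 24.3 (control) and 0, 27.5, 0 and 0 (obese). ENSOARG00000000727 had 10.5 ± 2.50 in BPA and 3.15 ± 1.95 in ObBPA hearts (SD, n = 4), a log2 difference of -1.57 ± 0.355 (SE). ENSOARG00000024827 had values of 23.4, 60.8, 37.4 and 55.6 in the BPA libraries and was listed at 0 in all 4 ObBPA libraries. In the groups not compared its values were 0, 0, 27.0 and 0 (control) and 0, 55.0, 0 and 0 (obese). The adjusted p by limma was 1 for all 4 features. No feature was called by limma, and 221 had an unadjusted p under 0.05, 124 higher and 97 lower, or 380 without control library 1 and 354 without ObBPA library 3. For 92.64% of features the 95% interval lay within a 2-fold change. With only these groups fitted, ENSOARG00000021237 and ENSOARG00000024827 were called.

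The combined exposure was compared with neither as ObBPA against control. ENSOARG00000012717 had a mean FPKM of 58.4 ± 4.42 in control, 69.9 ± 3.39 in BPA, 73.3 ± 1.60 in obese and 80.8 ± 3.0 in ObBPA hearts (SD, n = 4). Its log2 difference between ObBPA and control was 0.46 ± 0.0745 (SE), with an adjusted p of 0.263 by limma, the smallest in any contrast, and all 4 ObBPA libraries lay above all 4 control libraries. ENSOARG00000024410 was listed at 0 in all 4 control libraries and had values of 1519, 714, 3334 and 1436 in the ObBPA libraries. It also varied within groups, with 0, 0, 618 and 898 in the obese and 1387, 967, 0 and 1324 in the BPA libraries. ENSOARG00000007776 had 27.6 ± 2.91 in control and 20.9 ± 0.787 in ObBPA hearts (SD, n = 4), a log2 difference of -0.38 ± 0.0797 (SE). ENSOARG00000013830 had values of 1.11, 4.32, 2.58 and 1.16 in the control libraries and was listed at 0 in all 4 ObBPA libraries. The adjusted p of these 3 features was 0.941 by limma. No feature was called by limma, and 469 had an unadjusted p under 0.05, 280 higher and 189 lower. Without control library 0 or 2 that count was 1045, without control library 3 it was 806, and without ObBPA library 1 it was 299. For 91.94% of features the 95% interval lay within a 2-fold change. ENSOARG00000012717 was called under 4 of 32 alternatives, with an adjusted p by limma of 0.00431 to 1 over them, and ENSOARG00000024410 was called with only these groups fitted.

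Averaged over both diets, prenatal BPA gave no call by limma, with 224 features at an unadjusted p under 0.05, 128 higher and 96 lower, and a smallest adjusted p of 0.765. The number was 403 without control library 0 and 360 without control library 2. The smallest adjusted p belonged to ENSOARG00000014190, with a log2 difference of -0.67 ± 0.119 (SE). ENSOARG00000022773 was listed at 0 in all 4 BPA libraries and in ObBPA library 1, and had values of 15.7, 11.6 and 9.98 in the other ObBPA libraries. Its values were 25.5, 36.4, 17.2 and 25.0 in the obese libraries, and 48.9, 20.0, 0 and 21.5 in the control libraries. The feature with the smallest p among those higher, ENSOARG00000004890, was listed at 0 in all control and obese libraries and in ObBPA libraries 0, 2 and 3, and had 1.75 in ObBPA library 1 beside the BPA values above. ENSOARG00000001688 had a log2 difference of 0.58 ± 0.142 (SE). For 95.19% of features the 95% interval lay within a 2-fold change. Without BPA library 1, ENSOARG00000025092 was called.

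Overfeeding averaged over both prenatal treatments gave no call by limma, with 392 features at an unadjusted p under 0.05, 204 higher and 188 lower, and a smallest adjusted p of 0.999. The number was 752 without control library 0 and 655 without control library 2. ENSOARG00000012717 had a log2 difference of 0.27 ± 0.0527 (SE), and ENSOARG00000022720 one of 0.95 ± 0.215 (SE). ENSOARG00000020795 had a log2 difference of -0.44 ± 0.0934 (SE), with mean FPKM of 6.56 ± 1.01 in control, 5.37 ± 0.522 in BPA, 4.05 ± 0.907 in obese and 4.21 ± 0.243 in ObBPA hearts (SD, n = 4). ENSOARG00000013830 was listed at 0 in obese libraries 0 and 2 and had values of 1.31 and 1.35 in obese libraries 1 and 3. For 95.22% of features the 95% interval lay within a 2-fold change.

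The interaction asked whether the effect of prenatal BPA differed between the diets. ENSOARG00000026941 had a mean FPKM of 5.16 ± 0.786 in control, 3.56 ± 0.528 in BPA, 3.73 ± 0.629 in obese and 5.39 ± 1.14 in ObBPA hearts (SD, n = 4), an interaction of 0.85 ± 0.206 (SE) on the log2 scale. ENSOARG00000021045 had means of 7.04 ± 2.99 in control and 9.82 ± 2.11 in BPA hearts (SD, n = 4) beside the values of overfed animals above, an interaction of -1.95 ± 0.451 (SE). ENSOARG00000004490 had means of 2.40 ± 0.365, 3.36 ± 0.776, 3.17 ± 0.460 and 2.16 ± 0.434 in control, BPA, obese and ObBPA hearts (SD, n = 4), an interaction of -0.75 ± 0.196 (SE). ENSOARG00000025092 had values of 36.5, 0, 13.0 and 14.5 in the BPA libraries, beside the values of the other groups above. The adjusted p of the 4 features was 0.999 by limma. No feature was called by limma, and 360 had an unadjusted p under 0.05, 187 with a positive and 173 with a negative interaction, or 767 without control library 0. The median SE of the interaction was 0.223, and for 83.81% of features its 95% interval lay within a 2-fold change.

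Across the 13251 features, which are not independent replicates, the log2 differences of BPA against control and of ObBPA against obese had a Pearson correlation of -0.037 and a Spearman correlation of -0.12. As many as 43 of 100 regroupings of the animals gave a Pearson value as far from 0 (permutation p = 0.43, adjusted 0.43), and 40 of 100 did for Spearman (permutation p = 0.4, adjusted 0.68). For the overfeeding effect without and with prenatal BPA, the Pearson correlation was -0.056 (permutation p = 0.37, adjusted 0.43) and the Spearman correlation was 0.059 (permutation p = 0.68, adjusted 0.68). These were the 2 relations computed. Their regroupings ignored the library numbers, so a regrouped group could hold none or several of the libraries numbered 0, unlike the real groups. The spread of the regroupings can therefore include the difference of those libraries. Among the 12 libraries numbered 1 to 3, the Pearson correlations were -0.0029 for prenatal BPA and 0.046 for overfeeding.

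**Figure D3:**
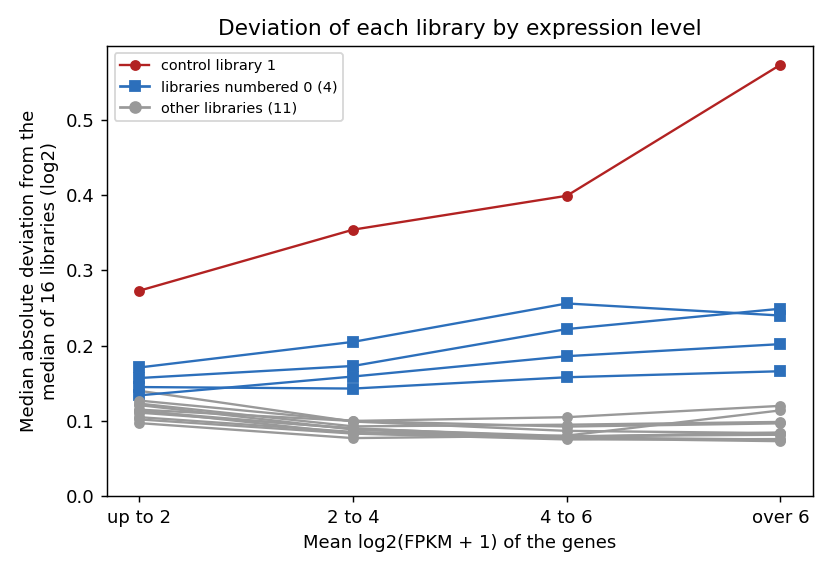
Median absolute deviation of each library from the median of the 16 libraries, in log2(FPKM + 1) (y axis), for features grouped by their mean log2(FPKM + 1) (x axis). Control library 1 reaches 0.573 in the highest class, and the others lie between 0.0731 and 0.249 there.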

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

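The comparison of the libraries numbered 0 with other choices of libraries, the count of calls after scaling and the comparison of 1-read steps were tests chosen after the difference had been seen. Of 111 groups of 4 libraries examined, 12 held a library far from the other 3. The rule used flags about 1 in 20 groups of independent, normally distributed values, or 5.6 here. Most groups were of features chosen by their p in these same data, some of them listed at 0 in part of the libraries. The 5.6 is therefore not a valid chance number for this set.

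In obese library 0, the median absolute deviation of features of high level was 0.249 on the log2 scale, against 0.0753 to 0.0816 in the other obese libraries. This library belongs to the set numbered 0, which differed from the rest in 3150 features. Only 1 of 100 choices of 1 library per group, the real one, gave as many, and the highest of the others gave 1. The other choices were a random draw and the test was chosen after the difference was seen. It argues against chance for this split but does not exclude it. A scaling offset as the whole cause is argued against by the 1601 features still called after median-of-ratios scaling, where the highest other choice gave 1; that test was added because the planned one, the share of calls that stayed, gave 34.3%, between the 20% and 50% set for it, and decided nothing, so an offset as a part of the cause stays open. An effect in some treatment groups stays open: of the features called from 3 groups at least 91% kept their sign in the group left out, past the 80% set for it, but most were lower in these libraries, as was the median of all features, and with differences centred on that median the share was 78.7% for control and 85.1% to 91.4% for the other groups. Differences in effective transcript length may contribute, since at most 10.9% of low features shared 1 step ratio between a library numbered 0 and another, against at least 49.0% between others, but pairs of libraries numbered 0 shared only 11.8% to 32.8%, which goes against 1 common length scale in these 4 libraries.

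Values of single features stood apart in 11 groups. ENSOARG00000004890 was at 1.46 on the log2(FPKM + 1) scale in ObBPA library 1 and listed at 0 in the other 3. ENSOARG00000014190 was lowest in ObBPA library 1, at 0.79 against 1.51 to 1.56. ENSOARG00000025092 was highest in control library 1, at 5.02 against 3.24 to 3.42. ENSOARG00000001688 was lowest in ObBPA library 3, at 5.17 against 5.82 to 5.95. ENSOARG00000022720 was lowest in obese library 0, at 7.76 against 8.18 to 8.26. ENSOARG00000021237 was at 4.83 in obese library 1 and listed at 0 in the other obese libraries. ENSOARG00000024827 was at 4.81 in control library 2 and at 5.81 in obese library 1, and listed at 0 in the other libraries of both groups. ENSOARG00000024410 was listed at 0 in BPA library 2, against 9.92 to 10.4 in the other BPA libraries. ENSOARG00000007776 was lowest in ObBPA library 2, at 4.37 against 4.47 to 4.48. ENSOARG00000022773 was listed at 0 in ObBPA library 1, against 3.46 to 4.06 in the other ObBPA libraries.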

How the results depend on the processing

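Alternatives with a term for the libraries numbered 0, without these libraries, without control library 1 beside that term, with that term and library weights, or with a filter on the median FPKM were chosen after seeing the data. The counts of 0 calls stayed at 0 with both other pseudocounts, both stricter filters, both scalings, without the variance trend, with robust variances, with the term for the libraries numbered 0 alone and among the 12 libraries numbered 1 to 3. Library weights were estimated from the residuals, and control library 3 had a weight of 3.82 against 0.114 to 0.892 in the other control libraries. They gave 1 call for BPA against control (ENSOARG00000003855, named after its values were seen), 6 for obese against control and 1 for ObBPA against control. That last was ENSOARG00000012717, also the 1 call without a filter, with the number 0 term and weights, and with that term and without control library 1; its adjusted p by limma was 0.0429, 0.00671 and 0.0261 there, within 0.00431 to 1 over its 32 alternatives. Fitting only the groups compared gave 1 call for ObBPA against obese, 4 for obese against control, 2 for ObBPA against BPA and 1 for ObBPA against control. These 8 calls were of ENSOARG00000025092 in the first pair of contrasts and of ENSOARG00000023569, ENSOARG00000023788, ENSOARG00000024105, ENSOARG00000021237, ENSOARG00000024827 and ENSOARG00000024410, each listed at 0 throughout 1 of the groups compared; the IDs outside the naming rule were named after their values were seen. The log2 difference is the same in both fits, 4.24 for ENSOARG00000025092 in ObBPA against obese, so only the estimate of spread changed. Each of these features mixed 0 with higher values in a group not compared, which widens the spread shared by all groups. ENSOARG00000025092, for example, had 36.5, 0, 13.0 and 14.5 in the BPA libraries. Where a library of a group not compared was left out, the log2 difference also stayed the same. It was 1.742 for ENSOARG00000004890 in BPA against control without ObBPA library 1. For ENSOARG00000025092 without BPA library 1 it was 4.24 in ObBPA against obese and -3.762 in obese against control. These calls did not come from a change in the difference. For the calls of the remaining alternatives the cause was not tested.

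With 1 library left out in turn, the counts ranged from 0 to 1 for BPA against control, ObBPA against obese, obese against control and prenatal BPA averaged over diets, and were 0 for the other contrasts. The calls were ENSOARG00000004890 in BPA against control without ObBPA library 1, ENSOARG00000012112 in obese against control without control library 3, and ENSOARG00000025092 without BPA library 1 in ObBPA against obese, in obese against control and in the averaged effect of BPA. The Spearman correlation was -0.124 for the BPA effect and 0.0587 for the overfeeding effect between the strata, and the Pearson correlation of the latter was 0.0457 among the libraries numbered 1 to 3; the cause was not tested. Of the other values, 243 counts and correlations were the same, and of the features printed 984 values kept their side of the threshold, 13 passed it in the same direction and 0 changed direction.

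The replicate numbers did not pair the samples: 1 of 6 pairs of libraries numbered 0 and none of the other pairs with a common number had deviations correlated over 0.1, and 7 of 16 libraries correlated best with their own number. The replicate block gave 0 calls in each of the 8 contrasts, with 340 to 927 features at an unadjusted p under 0.05. The gene list tests and their alternatives were not run, since no ID matched a name, and count models were not run on FPKM values. Depth limits the features of low level most, and its absolute value is unknown.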

Other observations

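The tests of low depth for control library 1, and of the libraries numbered 0 and control library 1 as the source of the shortfall of small p-values, were chosen after the patterns had been seen.

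Control library 1 stood apart from the other 15 libraries. For features with a mean log2(FPKM + 1) over 6, its median absolute deviation was 0.573, which is 5.92 times the median of the other libraries. Low depth is argued against as the whole cause, since the deviation grew with the level of the features, from 0.273 in the lowest class, although this library had the lowest relative depth, 0.539. A scaling offset is argued against by a ratio of 5.47 after median-of-ratios scaling. A difference in tissue sampled, RNA quality or the animal itself may stay open and was not tested, and control library 1 entered each contrast with control.

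All 8 contrasts gave fewer features at an unadjusted p under 0.05 than 663, the chance number if p-values are evenly distributed. Other splits of the animals, which ignored the library numbers, often fell below it too. Their median count was 284 for ObBPA against obese, 302.5 for ObBPA against BPA and 641 for obese against control. It was 467 and 430 for the averaged effects of BPA and overfeeding, 437 for the interaction, and 773 and 741 for BPA and ObBPA against control. With a term for the libraries numbered 0 and without control library 1, 8 of 8 contrasts reached 90% of the chance number. These libraries together may therefore contribute to the shortfall. The term alone gave 3 of 8 and leaving out control library 1 alone gave 0 of 8. Leaving out control library 0 alone gave 5 of 8, control library 2 alone 4 of 8 and control library 3 alone 2 of 8. The number under p 0.05 thus depended on single control libraries. These counts do not show that the shortfall lifted. Without control library 0, control held no library numbered 0 while the other groups kept theirs. Without control library 2 or 3, control library 1 weighed more in the control mean. With library weights and every library kept, 8 of 8 contrasts reached 90% of the chance number, with 807 to 1666 features. So did 8 of 8 with the term and weights, with 801 to 1307. The libraries numbered 1 to 3 alone gave 4 of 8, with 270 to 1019. The number under p 0.05 depends on how libraries are weighted, and the source of the shortfall stays open. The trend in the variance model is argued against as the cause, since 0 of 8 contrasts reached it without the trend.

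Other splits of the animals say nothing on chance for the counts of calls: with a real count of 0, all 35 splits of each pairwise contrast and all 100 regroupings of each of the other 3 contrasts necessarily gave as many. The highest of the other splits gave 1 call for BPA against control, 2 for ObBPA against obese, 1 for obese against control, 1 for ObBPA against BPA, 6 for ObBPA against control, 3 and 2 for the averaged effects of BPA and of overfeeding, and 2 for the interaction. At an unadjusted p under 0.05, the real split gave 324 features for BPA against control, the lowest of the 35, while for the other pairwise contrasts 19 of 35 splits gave as many for ObBPA against obese, 21 for obese against control, 25 for ObBPA against BPA and 29 for ObBPA against control. Of 100 regroupings, 97 gave as many for the averaged effect of BPA, 59 for that of overfeeding and 74 for the interaction. All of these splits ignored the library numbers. Some therefore put several libraries numbered 0 in the same group, whereas each real group held 1. Their counts can include the difference of those libraries, so these ranks cannot be read as a measure of chance for the balanced real groups. Some splits gave several times the real count, up to 2144, 2317 and 1857 for BPA, obese and ObBPA against control. Without control, splits reached 770 for ObBPA against BPA, where the real count was 221, and 722 for ObBPA against obese, where it was 260. The medians of the other splits in those contrasts were 302.5 and 284, so the highest counts were not typical. They can include the difference of the libraries numbered 0, and whether any other structure of the samples contributed was not tested.

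A hypothesis that overfeeding shifted many features slightly was prompted by an earlier look at how many features had groups without overlap among the libraries numbered 1 to 3. Among the 11 of these libraries other than control library 1, overfeeding averaged over prenatal treatments gave 869 features at an unadjusted p under 0.05. Regroupings of diet within prenatal treatment gave as many in 12 of 100, with a highest value of 1113, so the count does not exceed chance at the 5 in 100 set for it. For prenatal BPA the count was 582, reached in 57 of 100 regroupings, with a highest value of 1346. Small changes in many features are not excluded by either test.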
